A study of Mus musculus with 9 samples.

How the data were processed

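Gene expression was measured on Affymetrix U74Av2 arrays with RNA from the right forebrain of male C57BL mice, an inbred laboratory strain. Per the labels' protocols, 30 animals were divided into 3 treatments of 10 animals each. They received clozapine at 12 mg/kg/day, haloperidol at 1.6 mg/kg/day or no drug in the drinking water for 4 weeks after 2 weeks of acclimatisation. RNA from 9 animals, 3 per treatment, was hybridised without pooling, 1 animal per array. The titles and the series text name the right side of the brain, whereas the tissue entry of the labels names the left hemisphere, and the side was therefore not settled. Each array was assigned to its group and replicate number by its title.

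The deposited values are log2 probe set values made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects each probe's background from its sequence, normalises the arrays to each other and summarises the probes of a set. Its version and the probe set definition file were not given in the sources used here. Per-array medians of the deposited log2 values lay between 4.01 and 4.21. GCRMA pulls unexpressed probe sets towards a narrow floor, so small differences between low values can come from the background step. The number of arrays, not a read depth, limits the precision.

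The table held 12488 probe sets, of which 66 were Affymetrix control probe sets and entered no test. Of the other 12422, 10833 carried 1 gene symbol in the platform annotation, 396 carried several and 1193 carried none. Symbols were updated through the Entrez identifier to those of the RefSeq table of GRCm38.p6, which held 10817 of the 10833, and no coordinates were used because the array has no genome build. Probe sets with several symbols or none were tested but not named. They were kept for testing if their average over all 9 arrays was above the 40th percentile, a log2 value of 3.448. This left 7453 probe sets, of which 6708 with 1 symbol represented 5650 genes. In gene lists, each gene was represented by its probe set with the highest average.

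Tests used limma 3.58.1 in R 4.3.3. A linear model with 1 mean per treatment was fitted to all 9 arrays with lmFit and eBayes, giving 6 residual degrees of freedom and a prior of 2.03 degrees of freedom. The contrasts were clozapine minus control, haloperidol minus control and clozapine minus haloperidol, and a moderated F test covered the 3 groups. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 7453 probe sets with a threshold of 0.05. Gene lists written before the data were examined covered pathways, receptor families, cell types and brain regions. The 29 lists tested had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. Camera with an estimated correlation and the fry test were run as alternatives. Members of a list were also adjusted over the list alone. An exact permutation test of 3 arrays against 3 cannot give a two-sided p under 0.1. The arrays' same-sex labels were checked with Y-linked genes and Xist, and all 9 arrays had Eif2s3y between 7.01 and 8.16 and Xist between 2.76 and 3.16, while the Y-linked Kdm5d, at 4.02 to 4.32, and Uty, at 3.56 to 4.00, lay close to the filter value.

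The genes named were chosen by a rule fixed before the data were examined. Because no probe set passed the adjusted threshold, the rule took the 12 genes above and the 12 below with the lowest unadjusted p in each contrast, given as values that did not pass. It added the 3 genes with the lowest p of each list called by camera. It also added a fixed set of receptors, immediate early genes, neuropeptides and cell markers. Of that set, Drd1, Htr2a and Arc were among those unnamed on the annotated array, and Chrm4 and Adra1b were below the filter.

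The model was tested on simulated data with 200 of 7453 probe sets changed in the contrast of clozapine against control. It recovered 22.5% of changes of 0.5 log2 units, 68% of changes of 1 and 87.5% of changes of 2, with 1, 6 and 15 false calls. For these rates the noise was drawn independently for each probe set, whereas the real arrays share structure across probe sets. A simulation that kept this structure was also run, and its rates are not reported here. The rates given may therefore not hold for the real arrays. A list shifted by 0.5 in the simulation ranked 1 of 29, and 0 other lists were called. The noise of the genes was independent here too, so this check could not show false calls that come from correlated genes.

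Alternatives set before the data were examined covered the filter, a floor on low values, array centring, quantile normalization, an intensity trend with a robust prior, array weights, a fit to the 6 arrays compared, the replicate number as a block, a threshold of 0.10, the removal of probe sets with special suffixes and each array left out in turn. Alternatives added after seeing the data left out 2 arrays or used the 3' to 5' difference of control probe sets as a covariate. The correlation of the 2 drug responses was set beside 1000 simulations of unchanged groups with the same 3 controls. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used to join the tables and draw the plots.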

Results

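The study compared gene expression in the forebrain of mice given clozapine, an atypical antipsychotic, or haloperidol, a typical antipsychotic that blocks dopamine receptors, with that of untreated mice, to set the long-term profiles of the 2 drugs side by side. The drugs were given at 12 mg/kg/day and 1.6 mg/kg/day for 4 weeks, and these doses differ. Each group held 3 arrays from separate animals, and values are given as log2 values of the deposited GCRMA table. The median residual standard deviation of a probe set was 0.196 log2 units, and the median standard error of a difference between groups was 0.153. Correlations between arrays over the 7453 probe sets tested had a median of 0.9825 within groups and 0.9818 between groups, and the ranges overlapped, from 0.9472 to 0.9873 and from 0.9485 to 0.9941.

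Across the 3 groups, 0 of 7453 probe sets passed limma's moderated F test at an adjusted p of 0.05, and 251 had an unadjusted p under 0.05, where 372.7 were expected by chance. The first principal component held 50.1% of the variance and separated control replicate 3, at a score of 37.51, from the other 8 arrays. On the opposite side lay 1 array of each treatment, clozapine replicate 1 at -17.61, control replicate 1 at -19.63 and haloperidol replicate 3 at -19.75, and the other 5 arrays lay between 0.477 and 7.0. Control replicate 3 also had the largest gap between the 3' and 5' control probe sets of Actb and Gapdh, 1.73 log2 units, against 0.81 to 1.46 in the other arrays. The gap measures how far the labelled RNA leans to the 3' end of transcripts.

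**Figure D1:**
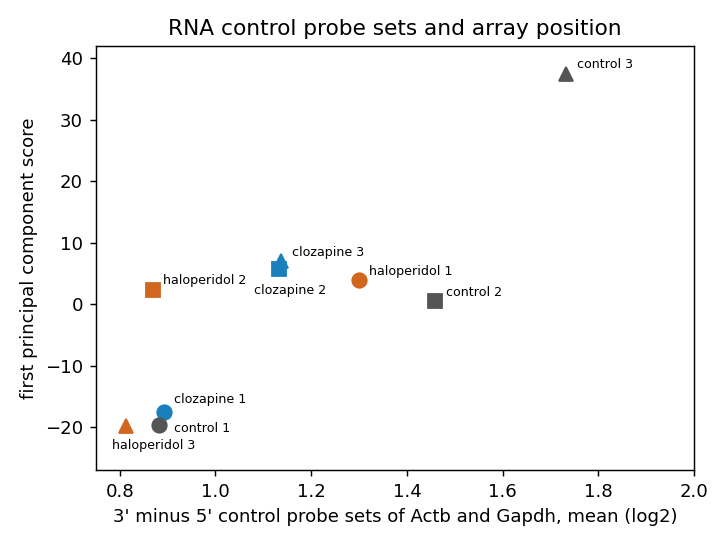
First principal component score of each array (vertical axis) against the mean 3' minus 5' difference of the Actb and Gapdh control probe sets in log2 units (horizontal axis), 1 point per array, coloured by treatment and shaped by replicate number. Control 3 lies alone at 1.73 and 37.51.

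In the forebrains of clozapine-treated mice no gene passed the adjusted threshold, and the genes with the lowest unadjusted p included Dbp, Per2, Arntl and Nfil3, whose common role in the daily clock was noticed after their values were seen. Dbp, a transcription factor driven by the clock, lay 0.74 ± 0.13 log2 units (SE, n = 3 per group) above the controls, a fold of 1.67, and Per2, a core repressor of the clock, lay 0.79 ± 0.24 above. Arntl, the clock activator also known as Bmal1, lay at -0.54 ± 0.17 and Nfil3, a repressor that acts on the sites Dbp binds, at -0.39 ± 0.15. For each of these 4 genes, which were picked by their p, the 3 clozapine arrays and the 3 controls did not overlap, as held for 3.43% of all tested probe sets where chance gives 10%. Limma called 0 of 7453 probe sets, with a lowest adjusted p of 1, and 70 probe sets had an unadjusted p under 0.05, 33 above and 37 below the controls, against 372.7 expected by chance. This count was 196 without control 3, 186 without control 1, 43 without control 2 and 39 without clozapine 2.

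Of the other genes with the lowest unadjusted p, those above the controls included Pradc1 at 0.38 ± 0.08, Psmd6, a subunit of the proteasome's regulatory particle, at 0.32 ± 0.09, Elavl2, a neuronal RNA-binding protein, at 0.34 ± 0.09, and Lxn, a carboxypeptidase inhibitor, at 0.41 ± 0.12. The non-coding RNA Tug1 lay 0.29 above, Ythdc1, a nuclear reader of methylated RNA, 0.53, Mrps15, a mitochondrial ribosomal protein, 0.37, Cnih1 0.33, Txnip 0.33 and Wdr26 0.59. The other 3 probe sets of Wdr26 gave 0.11, 0.34 and 0.35. Below the controls lay Zfr2 at -0.37 ± 0.10, Nt5dc3 at -0.31, Ly6e at -0.32, Inpp5b at -0.32, Dennd5a at -0.34 and Pla2g4f at -0.33. Second probe sets gave -0.0814 for Ly6e and -0.14 for Inpp5b. Atp6ap1, an accessory subunit of the vacuolar proton pump, lay at -0.53 in the named probe set and at -0.135 in a brighter one. Dnajc3, a chaperone of the endoplasmic reticulum, lay at -0.28 in the named probe set and at 0.26 in another, Cyhr1 at -0.29 and 0.18, and Cnbp at -0.30 and 0.05.

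**Figure D2:**
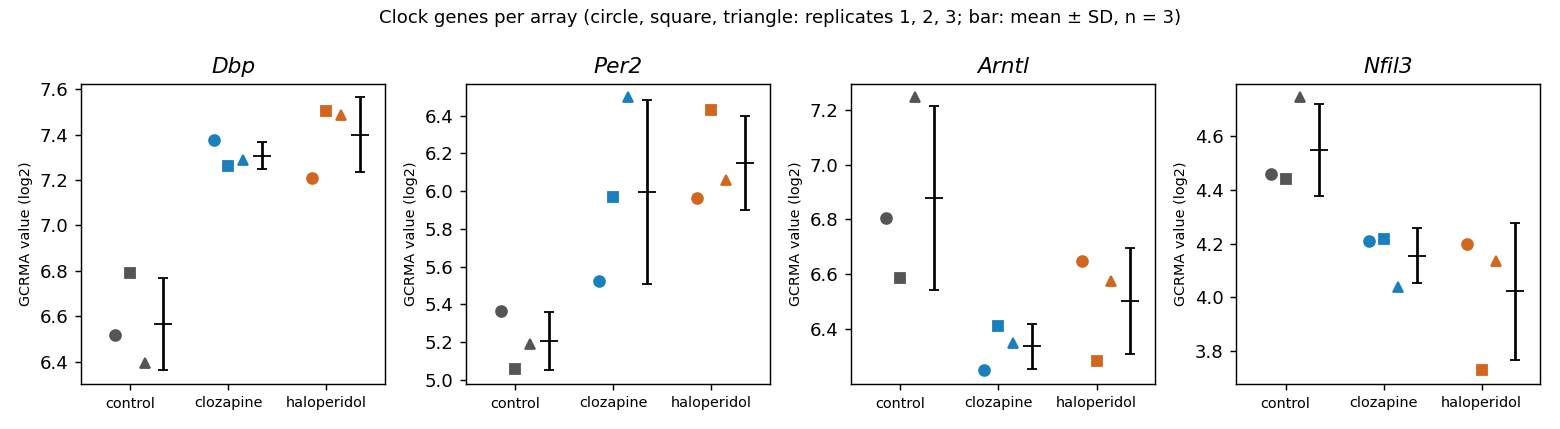
GCRMA values (log2, vertical axes) of Dbp, Per2, Arntl and Nfil3 in each array, by treatment, with replicates 1, 2 and 3 as circle, square and triangle and the mean ± SD (n = 3) beside them. The 3 controls of Dbp lie between 6.39 and 6.79 and the 6 treated arrays between 7.21 and 7.50.

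Of 29 gene lists, camera called 2 as higher with clozapine: genes of cortical and hippocampal excitatory neurons and genes of synaptic vesicles and exocytosis. In the first list 15 of 18 genes lay above the controls, with a median of 0.12 log2 units and an adjusted p of 0.0345 (adjusted p = 0.748 with an estimated correlation). In the second, 21 of 24 genes lay above, with a median of 0.15 and an adjusted p of 0.0345 (adjusted p = 0.748 with an estimated correlation). Fry called 0 lists, and 0 members passed when adjusted over the list alone or over all probe sets. The cortical genes with the lowest p were Ccn3 at 0.43 ± 0.19, Nr4a2 at 0.61 ± 0.33 and Crym at 0.33 ± 0.22, and those of the vesicle list were Vamp1 at 1.45 ± 0.97, Syn2 at 0.47 ± 0.35 and Stx1a at 0.55 ± 0.43. The value of Vamp1, a vesicle membrane protein, came from control 3 at 2.06 against 5.98 and 6.19 in the other controls, and its other probe set gave -0.09. Relative to the 9-array mean, control 3 lay at -0.52 for the cortical list and -0.57 for the vesicle list, while control 1 lay at 0.24 and 0.20. Without control 3 the medians were 0.03 and 0.04, with adjusted p of 0.618 and 0.605. With each of the 9 arrays left out in turn, the call was kept in 3 of 9 fits for the cortical list and in 4 of 9 for the vesicle list.

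**Figure D3:**
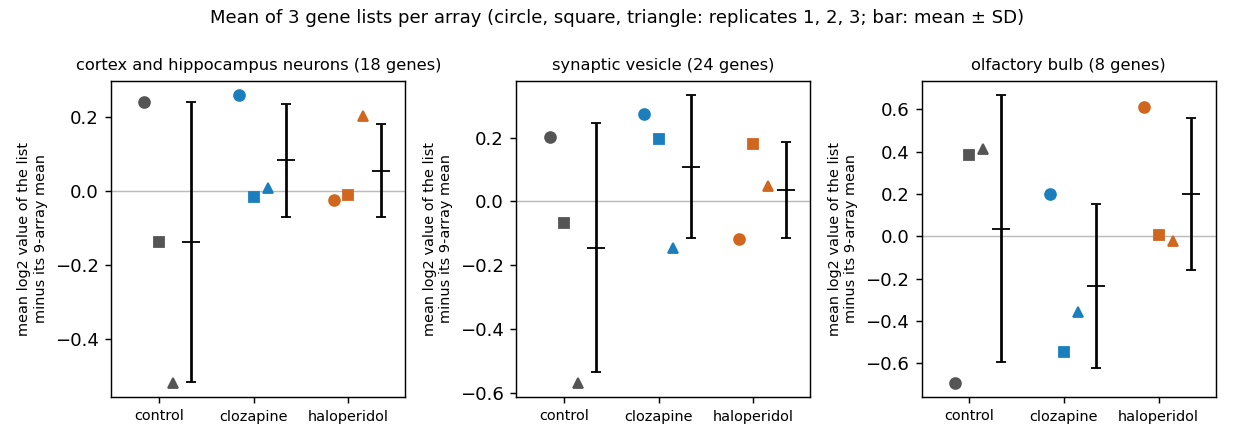
Mean log2 value of the genes of 3 lists in each array minus the mean over all 9 arrays (vertical axes), by treatment, with replicates 1, 2 and 3 as circle, square and triangle and the mean ± SD (n = 3) beside them. Control 3 is lowest in the cortical list, at -0.52, and in the vesicle list, at -0.57.

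The list of monoamine and muscarinic receptors had 3 of 5 genes above the controls with clozapine, with a median of 0.209 and an adjusted p of 0.241 in camera, and the immediate early genes had 16 of 22, with a median of 0.06 and an adjusted p of 0.344. The muscarinic receptor gene Chrm1, named after its value was seen, lay 0.90 ± 0.45 log2 units above. The dopamine receptor gene Drd2 lay 0.21 log2 units above (95% confidence interval -0.20 to 0.62) and the serotonin receptor gene Htr2c 0.27 above (-0.52 to 1.05). Without control 3 Drd2 was 0.0246, and Htr2c was 0.0129 without clozapine 1 and 0.556 without clozapine 3. The receptor list in control 3 lay at -0.526 relative to the 9-array mean, against 0.083 and -0.034 in the other controls. The immediate early genes Fos and Egr1 lay at 0.17 and 0.04, the opioid precursors Penk and Pdyn at -0.22 and 0.02, Mbp of myelin at 0.03 and Gfap of astrocytes at -0.19. Second probe sets had the opposite sign for Gfap, at 0.0625, Mbp, at -0.0105, and Pdyn, at -0.0724, and without control 3 the named Gfap probe set gave 0.107. None of these values passed the adjusted threshold. Genes of the olfactory bulb lay below the controls in 8 of 8 cases, with a median of -0.29 and an adjusted p of 0.205 in camera (adjusted p = 0.748 with an estimated correlation). At the preset correlation the adjusted p was 0.000167 without control 1, 0.00422 without clozapine 1 and 0.017 with array weights. The estimated correlation of this list was 0.493, against the preset 0.01, so these p-values are likely too small. Of the 8 genes, Gpsm1 and Th lay at -0.0025 and -0.0046. Control 1, at -0.69 relative to the 9-array mean, lay below all 3 clozapine arrays in this list. Cholesterol synthesis genes had 11 of 16 members above, with a median of 0.05, and oligodendrocyte and myelin genes had 6 of 14, with a median of -0.01.

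With haloperidol Dbp, Per2 and Nfil3 also stood among the genes with the lowest unadjusted p, on the same side of the controls as with clozapine. Both drugs were compared with the same 3 controls, so this is not an independent repeat. Dbp lay 0.83 ± 0.13 log2 units above (SE, n = 3 per group), a fold of 1.78, Per2 0.95 ± 0.24 above, and Nfil3 at -0.53 ± 0.15. Nfil3 had a low signal, with a control mean of 4.55, a range in which many haloperidol values lay below the controls. Its second probe set, below the filter, gave -0.141. Arntl, which the rule for named genes did not take for this contrast, had a mean of 6.50 ± 0.19 (SD) against 6.88 ± 0.34 in the controls. Pradc1, at 0.61 ± 0.08, had the lowest unadjusted p, 5.89e-05 by limma, with an adjusted p of 0.439. Limma called 0 of 7453 probe sets, and 680 had an unadjusted p under 0.05, 153 above and 527 below the controls, against 372.7 expected by chance. The count was 205 without haloperidol 3 and 161 without control 2, both under that expectation.

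Above the controls with haloperidol, Psmd6 lay 0.51 ± 0.09 above and Psma6, a subunit of the proteasome core, 0.45 ± 0.11. Adsl, an enzyme of purine synthesis, lay 0.58 ± 0.14 above, Lxn 0.64 ± 0.12, Ccdc88a 0.67 ± 0.17, Elavl2 0.40, Mrps15 0.50, Tbc1d15 0.46 and 4833420G17Rik 0.43. The second probe sets of Ccdc88a and Tbc1d15 gave -0.013 and 0.091. Below the controls lay Ly6e at -0.51 ± 0.10, Zfr2 at -0.50 ± 0.10, Nt5dc3 at -0.48 ± 0.10, Atp6ap1 at -0.64 ± 0.15 and Mapk8ip1, a scaffold of the JNK pathway, at -0.44 ± 0.11. A brighter probe set of Atp6ap1 gave -0.0677 and a second one of Ly6e gave -0.157. Pla2g4f lay at -0.52, Taf15 at -0.42, Flg at -0.67, Bmp2 at -0.57, Polk at -0.43 and Capn3 at -0.30, all with control means of 5.63 or lower.

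The excess of lower values with haloperidol lay among probe sets of low signal. Among the 1864 tested probe sets with the lowest averages, 3.45 to 4.61, the median difference from the controls was -0.13, and 371 of the 527 lower values at an unadjusted p under 0.05 fell there. Among the 1863 with the highest averages the median was 0.04, with 67 above and 26 below. With each array centred on its median, 405 lay above and 152 below, or 72.7% above against 22.5% as deposited. Of all tested probe sets, 21.7% had haloperidol arrays that did not overlap the controls, 171 above and 1445 below, where chance gives 10%.

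No gene list was called for haloperidol. The cortical list had 11 of 18 genes above the controls with a median of 0.12 (unadjusted p = 0.0349 and adjusted p = 0.769 in limma's camera), and the vesicle list 18 of 24 with a median of 0.13. Drd2 lay 0.28 log2 units above (95% confidence interval -0.13 to 0.69), Htr2c 0.35 (-0.43 to 1.13), Fos 0.17 and Egr1 0.03. Penk lay at 0.17, Pdyn at -0.06, Mbp at -0.14 and Gfap at -0.21. Without control 3 Drd2 was 0.0952 and Gfap 0.0885, and without haloperidol 3 Htr2c was 0.0669. Haloperidol replicate 3 alone had high values of pituitary hormone genes, with growth hormone (Gh) at 12.57 against at most 1.28 in the other 8 arrays and prolactin (Prl) at 11.76 against at most 3.84. The haloperidol mean of Prl lay 2.59 ± 1.95 above the controls for this reason, and the 5 genes of the hypothalamus and pituitary list had a median of 0.28.

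**Figure D4:**
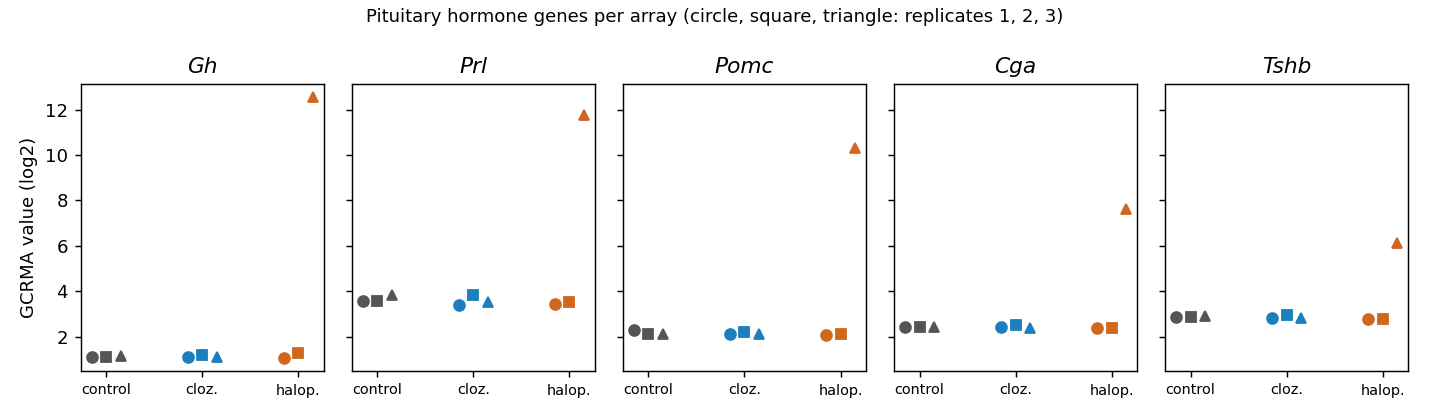
GCRMA values (log2, vertical axis) of 5 pituitary hormone genes in each array, by treatment, with replicates 1, 2 and 3 as circle, square and triangle. Haloperidol 3 stands alone in each panel, at 12.57 for Gh and 11.76 for Prl.

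Between the drugs, Penk, the enkephalin precursor of striatal neurons, stood among the genes with the lowest unadjusted p. It had a mean of 11.37 ± 0.10 with clozapine and 11.76 ± 0.16 with haloperidol (SD, n = 3), beside 11.59 ± 0.04 in the controls. The difference was -0.39 ± 0.10 (SE), with a limma adjusted p of 0.915 over all probe sets and 0.0614 adjusted over the list of striatal genes alone. A second Penk probe set gave -0.555. Limma called 0 of 7453 probe sets, and 271 had an unadjusted p under 0.05, 222 higher with clozapine and 49 lower, fewer than the 372.7 expected by chance. This count was 37 without clozapine 2, 48 without haloperidol 3, 132 without clozapine 3, 154 without control 1, 155 without control 2, 178 without control 3 and 445 without haloperidol 2. With each array centred on its median, 25 were higher with clozapine and 192 lower, with the filter at the 60th percentile 9 and 21, and with no filter 1989 and 72. Without clozapine 2 there were 14 higher and 23 lower, and without haloperidol 3 22 and 26. Leaving out any other single array kept more higher than lower. Which side held more of these probe sets thus depended on the scaling, on probe sets of low signal and on single arrays. The count was 585 with the intensity trend and robust prior.

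Among the genes with the lowest p on the lower side for clozapine, Adsl lay at -0.53 ± 0.14, Rabggtb, which attaches lipid to Rab proteins, at -0.47 ± 0.12, Tardbp, an RNA-binding protein, at -0.38 ± 0.11 and Nae1, of the NEDD8 conjugation pathway, at -0.30 ± 0.09. Tmem43 lay at -0.35, Ccdc93 at -0.26, Pnpt1 at -0.27, Rab5if at -0.28, 4833420G17Rik at -0.32, Ogn at -0.47 and Ppp1r18 at -0.43. Second probe sets gave 0.235 for Ccdc93, 0.00933 for Ogn and -0.261 for Tardbp. Of the genes higher with clozapine, Mapk8ip1 lay 0.33 ± 0.11 above and had a control mean of 9.35. The other 11, Pdc, Taf15, Scel, Flg, Zfp503, Ndufa1, Asl, Xpa, Brd7, Klk1 and Pcid2, lay 0.22 to 0.54 above, with control means of 4.02 to 5.63, a range in which many haloperidol values lay below the controls. Other probe sets past the filter gave 0.413 for Zfp503 and 0.288 for Pdc, of the same sign, and -0.421 for Xpa and -0.288 and -0.204 for Brd7.

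No gene list was called between the drugs. Olfactory bulb genes lay lower with clozapine in 7 of 8 cases, with a median of -0.495 (adjusted p = 0.314 in camera, 0.928 with an estimated correlation, and 0.0259, 0.0307 and 0.0178 at the preset one without clozapine 1, control 1 and haloperidol 3), and genes of the respiratory chain in 33 of 48, with a median of -0.06 (adjusted p = 0.418, 0.928 with an estimated correlation, and 0.0417 without clozapine 1 and 0.0262 with no filter at the preset one). Drd2 differed by -0.07 (95% confidence interval -0.48 to 0.34), Htr2c by -0.09 (-0.87 to 0.70), Fos by 0.00114, Egr1 by 0.00769, Pdyn by 0.08, Mbp by 0.17 and Gfap by 0.02.

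The 2 drug responses were correlated across the 7453 probe sets, with a Pearson r of 0.682 and a Spearman rho of 0.635, and 72.4% of probe sets had the same sign. Both responses are measured against the same 3 controls, and probe sets are not independent replicates. Unchanged groups simulated against shared controls gave a median r of 0.567 (95% of simulations between -0.627 and 0.955) and a same-sign share of 69.1%. The observed covariance was 0.0263 against a simulated mean of 0.0319, a difference of -0.0056. The controls could not be split into sets of at least 2 arrays, so the correlation was not measured apart from the shared controls.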

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

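The tests of 3' bias and of a response to haloperidol were chosen after the results were seen, and the other tests before. Among 5035 probe sets that entered no comparison, 9 values of single treated arrays lay over 3 log2 units above the highest control. In haloperidol replicate 3 these were Gh at 12.57, Pomc at 10.31, Cga at 7.63 and, in a second probe set, 7.89, and Tshb at 6.14. In haloperidol replicate 2 they were the 18S ribosomal RNA control probe sets at 10.88, 9.35 and 8.97, against at most 2.83 in the controls, and the antisense probe set of Gapdh at 9.54. The Gapdh value was not particular to that array: clozapine replicate 2, short of the step, had 8.52, against 5.14 to 6.35 in the remaining arrays.

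Gh, Prl and other pituitary hormone genes were high in haloperidol replicate 3 alone. A response to haloperidol is argued against by Prl in haloperidol 1 and 2, of which the nearer to the controls lay -0.289 from the highest control. Pituitary tissue carried into the sample may account for them: of Pomc, Cga, Lhb, Fshb and Tshb, a list set from Gh and Prl before these 5 genes and the values above other than Gh were looked at, 3 lay over 1 log2 unit above the highest of the other 8 arrays. Lhb and Fshb did not, at 0.79 and 2.63, and their probe sets stayed at the level of the other arrays. Whether other genes of this array carry pituitary RNA was not tested.

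Control replicate 3 lay apart from the other arrays on the first principal component. With a smaller share of cortex in the sample, the myelin, striatal and thalamic lists should lie higher. This was not seen: they had medians above the other controls in 0 of 3 cases, at -0.22, -0.08 and -0.04. The median was -0.38 for the cortical list and -0.02 for all genes tested. Other lists did lie higher. Relative to the 9-array mean, the astrocyte list was at 0.17 in control 3 and at 0.04 and -0.023 in controls 1 and 2. The cerebellum list was at 0.201 against -0.064 and -0.068. A different make-up of the sample was therefore not excluded. A 3' bias of the labelled RNA may account for the position of control 3: over 9 arrays the component followed the 3' to 5' gap with Pearson r = 0.845 (exact permutation p = 0.00518) and Spearman rho = 0.70 (exact permutation p = 0.0433). Without the 2 arrays farthest from the median gap, controls 2 and 3, r was 0.75, and without control 3 alone it was 0.656. A biological difference of this animal was not tested.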

How the results depend on the processing

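The settings that left out 2 arrays or used the 3' to 5' covariate were chosen after seeing the data. The counts of 0 probe sets past the adjusted threshold, in the F test and in the 3 comparisons, held in limma under every alternative run, beside 251 probe sets at an unadjusted p under 0.05 in the F test and 70, 680 and 271 in the comparisons, and no named gene passed under any of them, with a lowest adjusted p of 0.0632, under array weights. The array weights did not converge and gave control 2 a weight of 13.6. Same-numbered arrays did not deviate together throughout: their correlations ran from -0.597 to 0.697, 3 of 9 were over 0.1 and 5 of 9 arrays were closest to an array of their own number. The highest were 0.697 for clozapine 1 with control 1 and 0.692 for clozapine 2 with haloperidol 2. Arrays of different numbers came close to these, at 0.661 for clozapine 1 with haloperidol 3 and 0.651 for clozapine 3 with haloperidol 1. The numbers thus did not pair all animals, and a partial pairing stays open. The replicate block left the counts at 0 probe sets in each comparison and at 2, 0 and 0 lists. The unadjusted counts moved more. Array weights gave 926 for clozapine and 1891 for haloperidol against control, and the 3' to 5' covariate gave 358 for clozapine. Quantile normalization gave 149 above and 319 below for haloperidol against control and 47 and 60 for clozapine against haloperidol. The haloperidol count depended on probe sets of low signal: with no filter 180 lay above the controls and 1764 below, and with the filter at the 60th percentile 110 above and 72 below.

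The 2 list calls for clozapine against control, the only calls of the main fits, changed with the setting. The count was 0 with no filter, with the 6 arrays compared, without probe sets of special suffixes, with an estimated correlation, with fry and without control 3 and haloperidol 3, it was 1 with the 3' to 5' covariate and 5 with array weights. With 1 array left out it ran from 0 to 3: 0 without control 3, haloperidol 1 or haloperidol 3, 1 without clozapine 2, and 3 without clozapine 1 or control 1. The 3 without clozapine 1 were olfactory bulb, respiratory chain and ribosomal protein genes, all lower, with both reported lists lost, and the 5 with array weights held the cortical list and not the vesicle list. The call with the covariate was of ribosomal proteins, as lower. For clozapine against haloperidol, where 0 lists were called, 1 was called with no filter, with the 6 arrays compared, without control 3 and haloperidol 3, and with the covariate, and 0 to 2 with 1 array left out, 2 without clozapine 1 and 1 without haloperidol 3 or control 1. The adjusted p of the cortical list ran from 0.000733, without control 1, to 0.938, with the covariate, and that of the vesicle list from 0.0064, without clozapine 3, to 0.928, with fry. The shared-response correlation ran from 0.382, without clozapine 1, to 0.861, without control 1. Apart from fewer arrays or genes tested, the cause was not tested.

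Sign changes were seen in 18 of 101 comparisons of named genes, all among 7 genes of the fixed set, whose reported differences in these comparisons ran from -0.206 to 0.351. Centring gave Pdyn 0.0399 for haloperidol against control and, for clozapine against haloperidol, Fos -0.098, Egr1 -0.091, Pdyn -0.020 and Gfap -0.081. Quantile normalization gave Pdyn -0.011 for clozapine and Egr1 -0.0053 for haloperidol against control. Array weights gave Gfap 0.119 and 0.084 against control and Egr1 -0.0099 between the drugs. Without control 3 and haloperidol 3, Gfap was 0.107 for clozapine against control, Drd2 -0.037 and Htr2c -0.119 for haloperidol, and Drd2 0.062, Htr2c 0.198, Fos -0.146 and Egr1 -0.057 between the drugs. The covariate gave Htr2c -0.049 and Mbp -0.089 for clozapine, Htr2c -0.025 for haloperidol, and Fos -0.055, Egr1 -0.0052 and Gfap -0.0077 between the drugs. With 1 array left out, clozapine against control ran from -0.052 to 0.333 for Fos, -0.012 to 0.077 for Egr1, -0.0097 to 0.035 for Pdyn, -0.092 to 0.146 for Mbp and -0.348 to 0.107 for Gfap. Haloperidol against control ran from -0.107 to 0.332 for Fos, -0.043 to 0.095 for Egr1 and -0.366 to 0.089 for Gfap. Between the drugs the ranges were -0.144 to 0.062 for Drd2, -0.338 to 0.205 for Htr2c, -0.219 to 0.275 for Fos, -0.057 to 0.081 for Egr1 and -0.075 to 0.116 for Gfap. The other named comparisons kept their sign in each alternative.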

Other observations

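The tests of 3' bias were chosen after the result was seen, and the test of further clock genes and the counts of other splits before. Genes of the olfactory bulb and its neuroblasts, a list fixed before the data were examined, spread widely among animals of 1 treatment. Their mean over 8 genes, relative to the 9-array mean, was -0.69 in control 1 and 0.39 and 0.41 in the other controls, 0.61 in haloperidol 1 and -0.55 in clozapine 2. The mean of 2 haemoglobin genes lay between -1.18 in haloperidol 1 and 0.78 in clozapine 1. Of 3 clock genes not looked at before, Nr1d2 lay between 8.67 and 9.418 in the treated arrays and between 8.004 and 8.795 in the controls. Tef in controls 1 and 2, at 8.445 and 8.376, lay inside the treated range, and Clock in control 3, at 6.821, lay below 5 of the 6 treated arrays.

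A score of Dbp, Per1 and Per2 minus Arntl and Nfil3, genes picked because of their values, was 1.66 ± 0.25 (SD) in the 6 treated arrays and 0.51 ± 0.31 in the 3 controls. Nfil3 had a low signal, where many haloperidol values lay below the controls. With the 3' to 5' gap as a covariate, the treated minus control difference of this score remained, at 0.9999 ± 0.213 (SE), after 1.145 ± 0.188 without it. Because the genes were picked for their difference, the score cannot decide whether a straight-line 3' bias is the whole cause. Another form of 3' bias stays open as well, because a single control, control 1, had a gap inside the treated range. The score of control 1 lay 0.806 below the lowest treated array. In the combined score of the further genes, Nr1d2 and Tef minus Clock, to which they did not contribute alike, the treated arrays lay 0.4522 above the controls (two-sided exact permutation p = 0.0357 over 84 splits, smallest possible 0.0119), or 0.3745 ± 0.17 with the covariate, although control 1 at 1.368 lay above clozapine 3 at 1.319. The clock was picked from values of these same arrays, and clock genes can vary together within an animal. That p is therefore not an independent test and cannot exclude chance. A shift of the daily clock between treated and control animals may underlie these values, as a hypothesis, and whether it would come from the drugs or from the time of day at death was not tested, since the labels give no time.

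Counts were also made for other splits of the arrays. The F test was run on 100 of the 280 partitions into 3 sets of 3, the real one included. The real count of 0 probe sets past the adjusted threshold tests nothing, since any split, and so all 100, must reach it. At an unadjusted p under 0.05, 48 gave at least the real 251, so chance cannot be excluded for that count. The highest, with 472 past the adjusted threshold and 2219 unadjusted, set clozapine 1, haloperidol 3 and control 1 against clozapine 2, haloperidol 2 and control 2 and against clozapine 3, haloperidol 1 and control 3. It points to a structure of the samples that crosses the treatments, for which the labels give no batch. Clozapine 2 and haloperidol 2, in 1 set of this split, were each other's closest arrays (r = 0.9926) and had the highest antisense Gapdh values. The main model did not include this structure, and only the replicate number was tried as a block. Whether the counts of 0 depend on it was not tested.

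Between 2 groups only 10 splits exist, the real one included. These are too few for a share under 0.05, and a real count of 0 is again reached by any split. For clozapine against control, 10 of the 10 splits gave at least 0 probe sets past the adjusted threshold (highest other 1), 9 gave at least the real 70 unadjusted (highest other 1175) and 5 gave at least the real 2 lists (highest other 6). For haloperidol against control these were 10 for the real 0 (highest other 0), 4 for the real 680 (highest other 1116) and 10 for the real 0 lists (highest other 4). Between the drugs they were 10 for the real 0 (highest other 0), 5 for the real 271 (highest other 634) and 10 for the real 0 lists (highest other 3).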
